A study of Drosophila melanogaster with 2 samples.

How the data were processed

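The series holds anti-GFP ChIP-seq of whole klu-eGFP transgenic embryos of 0 to 24 h, fragmented by sonication per the labels, in 2 biological replicates that the labels number 1 and 2. Both belong to 1 group, and groups and replicate numbers were taken from the labels. No control library was analysed here.

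The authors deposited 8 peak lists, all in dm6 per the labels. For each replicate there is a ranked list of all candidate peaks and a thresholded list, and for the series there are 2 ranked and 2 thresholded lists, the longer of the latter called the pooled list below and the shorter the conservative list. The file types named in the deposited text files include irreproducible discovery rate (IDR) ranking, which scores how well peaks are found again between 2 input lists. Per the deposited text files, the lists of both replicates derive from their own alignments and from 1 further file that both share, and the thresholded lists also from a file of unnamed type. Aligner, peak caller, IDR settings and versions are not given in the sources used here. The deposited score (column 5) runs to 1000, and the thresholded lists hold only peaks with a score of 830 or more. The deposited signal (column 7) is a height per peak whose scale is not given in the sources used here. Signals served to describe, rank and split peaks within a list and to correlate both replicates. Columns in −log10 of a q-value or of the IDR, as the authors deposited them, were read for their ranges only. All 3126 peaks of the pooled list were found at the same position and score in 1 of the ranked lists, whose 3309 peaks at or above that score included 183 more, 111 of them on the main arms. The lists give no read counts, so the depth per sample is unknown, and intervals on shares of peaks cover counting error over peaks only. How deep the sequencing was affects how many peaks a list holds.

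Peaks on arms X, 2L, 2R, 3L, 3R and 4 were used, and 39 pooled peaks on Y and on scaffolds were left out. Arm lengths in the reference genome (BDGP release 6, the assembly of dm6) covered every deposited peak end on the arms. Gene models came from Ensembl release 115 (BDGP 6.54), without transposon genes. A summit within 500 bp of an annotated start of any gene was a promoter summit, and the other classes followed in the order 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. A protein-coding gene was bound when a summit lay within 1 kb of one of its starts. For 11 list members an older symbol was matched to the current one, and all list members were found.

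The main list for each analysis was the pooled list. The tests, the 20 gene lists, the 15 motifs, the rule for named genes and most alternatives were chosen before the data were examined. Replicate overlap was the share of the shorter replicate list that overlapped the other by at least 1 bp, against 1000 circular shifts per arm, one-sided. Signals were correlated on the log2 scale with 100000 permutations, and again without the 2 farthest peaks. Peaks per arm were tested with an exact binomial test, classes against 1000 draws of random positions with the same number per arm, and promoter against other signal with 100000 permutations of the median difference and 1000 bootstrap draws for its SE. Motifs and 7-mers on either strand were counted within 50 bp of the summit and in a window of the same width 1 kb away, on a side drawn at random per peak, with an exact McNemar test. The sequences of the most significant 7-mers against flanks are not reported here. Gene lists were tested against 10000 random lists matched on number of distinct starts (1, 2, 3, or 4 and more) and gene length in 5 classes. P-values were adjusted by Benjamini-Hochberg within each family (arms, classes, motifs, 7-mers, lists) at a threshold of 0.05. Tests across peaks or genes treat them as independent, which they are not in full, and say nothing about the spread between embryo collections.

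The named genes are klu, the protein-coding genes with the nearest start to the 25 peaks of highest signal in both the pooled and the conservative list, and up to 4 bound members of each gene list with the highest signal. The per-replicate signal of a named peak is that of the overlapping peak with the nearest summit in the ranked list of that replicate.

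The alternatives were the conservative list, the peaks above the median signal, each replicate's own list (leaving out the other replicate), other overlap rules, promoter distances of 250 bp and 1 kb, a gene distance of 500 bp or the nearest start at any distance, windows of 25 and 100 bp, a flank 2 kb away, GC-matched random positions, a longer Klu/EGR site, ranked peaks below the threshold as the background, and gene number per arm as the expectation. Lists without overlapping secondary peaks (peaks that overlap a stronger one), gene lists without peaks within 20 kb of klu, GC-matched positions for all motifs and 7-mers, and windows of 25 bp for motifs other than Klu/EGR were added after seeing the data.

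Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9, with fixed random seeds. Each test was first tested on simulated data. For the 7-mer test on 3087 windows, 20 of 20 planted 7-mers among 8192 were recovered and 0 were called without planting. Both sets of simulated windows had the same base composition, unlike the real summits and flanks. The 0 calls therefore say nothing about calls that follow from GC content. For the overlap of 1511 peaks with 80% planted, the test returned 80.3%. For the promoter share of 3087 positions, a planted excess of 34.6 percentage points came back as 35.3. For gene lists among 13945 genes, 2% of random lists of 20 passed, and 100% of lists with 10 bound members did. For the median difference over 3087 values, a planted 0.35 came back as 0.36, and for the correlation over 1200 values, a planted r of 0.7 came back as 0.699. For motifs, 4.1% of 1000 draws without a difference passed, and 100% of 200 draws with shares of 8% against 4% did. For the arms, 3.25% of arms passed in draws of 3087 positions by arm length, and X drawn at 1.3 times its length passed in 100% of draws.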

Results

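Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of 0 to 24 h that expressed Klumpfuss fused to enhanced green fluorescent protein (klu-eGFP), with an antibody against the fluorescent protein. Klumpfuss (Klu) is a zinc finger transcription factor of the EGR/WT1 family with known roles in neural stem cells (neuroblasts) and sensory organs. The samples formed 1 group of 2 biological replicates, and no control library was analysed here. The labels name the target and the antibody but no comparison, so the report describes where the peaks lay, how far both replicates found the same places, and which genes and sequences lay under them. The lists hold no read counts, so the depth of each library is unknown. All positions are in the dm6 assembly, counted from 1.

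The pooled list of the series held 3126 peaks, of which 3087 lay on the 6 main chromosome arms and were used below. The shorter conservative list held 2413 peaks, and the lists of replicate 1 and replicate 2 on their own held 1553 and 2585. Of the pooled peaks on the main arms, 1274 overlapped a peak in the lists of both replicates (41.3%), and 654 overlapped a peak in neither (21.2%). Most pooled peaks were 400 bp wide (85.2%), and 7.13% overlapped a stronger peak of the same list.

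Both replicates found largely the same places. Of the 1511 peaks of replicate 1 on the main arms, 1240 overlapped a peak of replicate 2 by at least 1 bp, a share of 82.1% (95% Wilson interval 80.05 to 83.9%). Shifting the peaks along each arm gave a mean share of 1.15% and a highest share of 2.51% in 1000 shifts (one-sided permutation p = 0.000999, the smallest they can give). From the side of replicate 2, which has the longer list, 1314 of 2561 peaks were shared (51.3%). Signal in the shared peaks rose together in both replicates, with a Spearman rho of 0.710 and a Pearson r of 0.635 on the log2 scale across 1240 peaks, which are not independent replicates (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 peaks farthest from the median, rho was 0.710 and r was 0.645.

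The strongest peaks lay mostly at promoters, close to the start of the nearest gene. The 25 peaks of highest signal found in both series lists all overlapped a peak in the list of each replicate. Of these 25 summits, 18 lay in promoters (within 500 bp of an annotated start), 6 in introns and 1 in a non-coding exon, and 15 lay within 150 bp of a start of the named gene. The peak of highest signal, 1835 in the pooled list, 885.0 in replicate 1 and 959 in replicate 2, had its summit at 3L:19590614, in the promoter 90 bp upstream of CG14100 (peak 19590438 to 19590804). The next lay in the promoter of mRpL41, a protein of the mitochondrial ribosome, at 2R:15217760 with a signal of 1708, and in the promoter of the nucleotide-sugar transporter gene Ugalt at X:2703894 with a signal of 1628. Peaks in the promoters of mRpS10 (3R:15229543, signal 1130) and mRpL23 (3L:2373622, signal 886) belonged to the same group of mitochondrial ribosomal proteins. Among chromatin and transcription genes were an intron of the transcription factor gene Adf1 (2R:6663064, signal 1187), an intron of Trl, which encodes the GAGA factor (3L:14759518, signal 1120), the promoter of the Polycomb group gene ph-p (X:2137332, signal 1085), the promoter of Chro (3L:22878895, signal 1021) and an intron of the kinase gene Tlk (X:3742206, signal 934). An intron shared by HmgZ and HmgD, which encode HMG-box proteins, held a peak at 2R:21703397 with a signal of 1136. Further promoter peaks lay at Tcs5 (signal 1401), CG7601 (signal 1135), CG5611 (signal 1082), l(3)73Ah (signal 1008), Atat (signal 985), CenG1A (signal 959), PNPase (signal 958), eIF6 (signal 934), Fkbp14 (signal 859), cu (signal 850.5) and CG8320 (signal 847). Introns of CG11050 (signal 1583) and CG32772 (signal 921) held the others, together with a non-coding exon 5044 bp from the nearest protein-coding start, that of CG4004 (signal 1154). Each signal is the authors' value per peak.

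At the klu gene itself (FBgn0013469, 3L:10981171 to 11009188, minus strand), a peak lay in the promoter 151 bp upstream of a start (summit 3L:11009339). Its signal was 108 in the pooled list, 46.8 in replicate 1 and 58.7 in replicate 2, and the peak was in the lists of both replicates. Altogether 17 pooled peaks had their summits within 20 kb of the gene, 1 in the promoter, 6 in introns, 1 in a coding exon and 9 in intergenic sequence. Their signals ran from 22.1 to 136, with a median of 87.8 against 106 for all pooled peaks. The highest signal of 136 belonged to an intergenic peak at 3L:10965759 to 10966158. The list of replicate 1 alone held 7 peaks in this region, that of replicate 2 held 5, and the conservative list held 10.

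**Figure D1:**
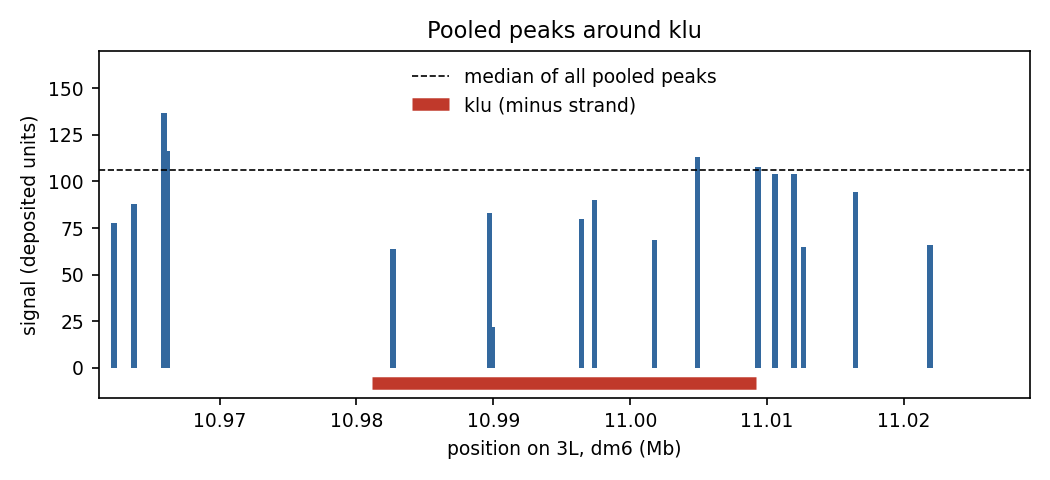
Peaks of the pooled list within 20 kb of klu. The x axis is the position on 3L in Mb (dm6), the y axis the deposited signal, each blue bar a peak drawn to its width, the red bar the gene and the dashed line the median of all pooled peaks at 106. The 17 peaks reach signals of 22.1 to 136.

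Summits were concentrated at promoters. Of the 3087 summits, 1583 lay within 500 bp of an annotated transcription start, a share of 51.3% (95% Wilson interval 49.5 to 53.04%), against a mean of 13.6% and a highest value of 15.4% in 1000 draws of random positions on the same arms. Coding exons held 1.49% of summits against 13.7% of random positions, 3' UTRs 0.583% against 4.45%, introns 32.8% against 39.5%, and intergenic sequence 12.7% against 27.2%. These differences had an unadjusted two-sided permutation p of 0.002, the smallest that 1000 draws can give, and a Benjamini-Hochberg adjusted permutation p of 0.0028 over the 7 classes. The classes exclude each other and promoter comes first, so the promoter excess lowers the shares of the other classes. Lower shares therefore do not by themselves show that summits outside promoters avoid introns or intergenic sequence. Of the 1504 summits outside promoters, 1011 lay in introns, which was not tested against random positions outside promoters. The 5' UTRs outside promoters held 0.356% of summits against 0.784% (adjusted permutation p = 0.00466), and non-coding exons held 0.842% against 0.808% (adjusted permutation p = 0.895). The 5' UTR difference did not pass in the conservative list (0.419% against 0.786%, adjusted permutation p = 0.0699), in the list of replicate 1 alone (0.596% against 0.788%, adjusted permutation p = 0.533) or with promoters of 250 bp (0.972% against 1.33%, adjusted permutation p = 0.103). The share in coding exons was 0.469% in the list of replicate 2 alone, 1.19% in that of replicate 1, 0.671% in the conservative list and 0.324% in the peaks above the median signal, and its difference passed in each. Ranked peaks that did not reach the threshold lay in promoters at a share of 12.9%. Promoter peaks were also stronger than the others, with a median signal of 122 against 95.3, a difference of 0.35 ± 0.03 in median log2 signal (bootstrap SE, 1583 and 1504 peaks, two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). From the strongest to the weakest quintile of the peaks, the promoter share fell from 69.4% to 39.2%.

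**Figure D2:**
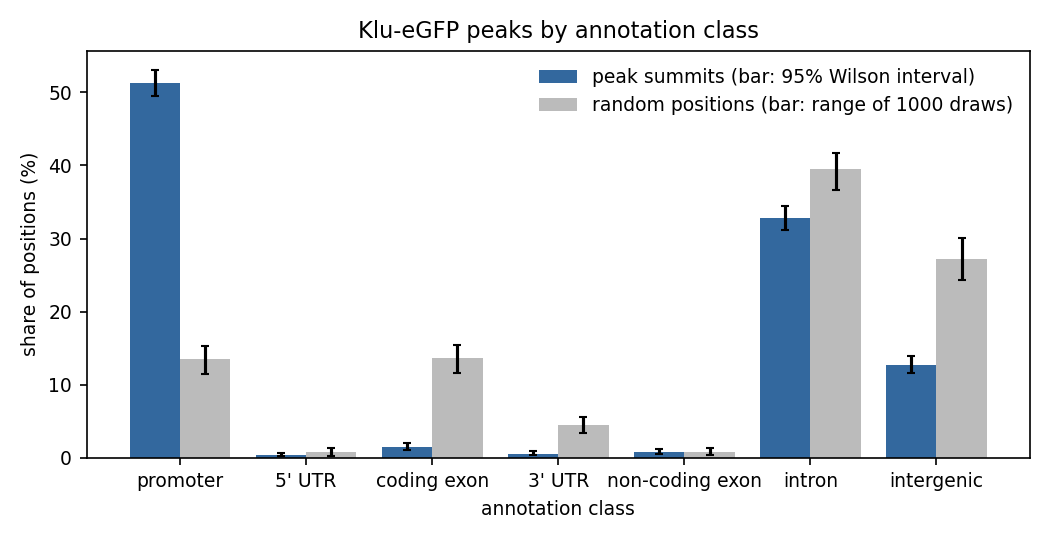
Share of positions in each annotation class (y axis, percent) for the 3087 pooled summits in blue, with 95% Wilson intervals, and for random positions in grey, with the range of 1000 draws. Promoters hold 51.3% of summits and 13.6% of random positions, while coding exons hold 1.49% and 13.7%.

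The peaks were spread over the large arms nearly in proportion to length, and chromosome 4 was almost empty. Chromosome 4 held 1 peak where 31.1 were expected by length, 0.0324% of all peaks (95% exact interval 0.00082 to 0.180%, exact binomial test, adjusted p = 1.03e-11). The X chromosome held 597 peaks where 543 were expected, a ratio of 1.10 (exact binomial test, p = 0.0114, adjusted p = 0.0342 over 6 arms). The ratio on X was 1.04 in the list of replicate 2 alone, where the exact binomial test no longer passed (adjusted p = 0.453), and 1.18 in the list of replicate 1 alone. In the peaks above the median signal the ratio was 1.11 (exact binomial test, adjusted p = 0.0828). Arms 2L, 2R, 3L and 3R had ratios of 1.02, 0.972, 1.01 and 0.960, and the lowest of their adjusted p-values by the exact binomial test was 0.427.

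Of 13945 protein-coding genes on the main arms, 2243 (16.1%) had a summit within 1 kb of a start. The genes of cytoplasmic ribosomal proteins stood out among the 20 lists. This list had been chosen beforehand as a housekeeping control, and the random lists were not matched on expression. Of 92 ribosomal protein genes, 41 had such a peak, against a mean of 15.3 and a central 95% range of 9 to 22 in 10000 random lists matched on number of starts and gene length (two-sided permutation p = 2e-04, the smallest these draws can give, adjusted permutation p = 0.004). The 4 with the highest signal were RpL34b (358, 3R:9401350), RpS27 (326, 3R:25247565), RpL23A (258, 3L:1668757) and RpL32 (256.3, 3R:30046320), each in a promoter and each in the lists of both replicates, and the peak of RpL32 lay nearer to a start of CG7943. For 32 of the 41 genes the strongest peak was nearer to their own start than to that of any other protein-coding gene. This result rested on replicate 2: its list alone gave 40 bound ribosomal protein genes, and the list of replicate 1 alone gave 16 against a matched mean of 9.01, with an unadjusted permutation p of 0.0266 and an adjusted permutation p of 0.266. Without replicate 2 the number of genes with a summit within 1 kb of a start was 1250.

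**Figure D3:**
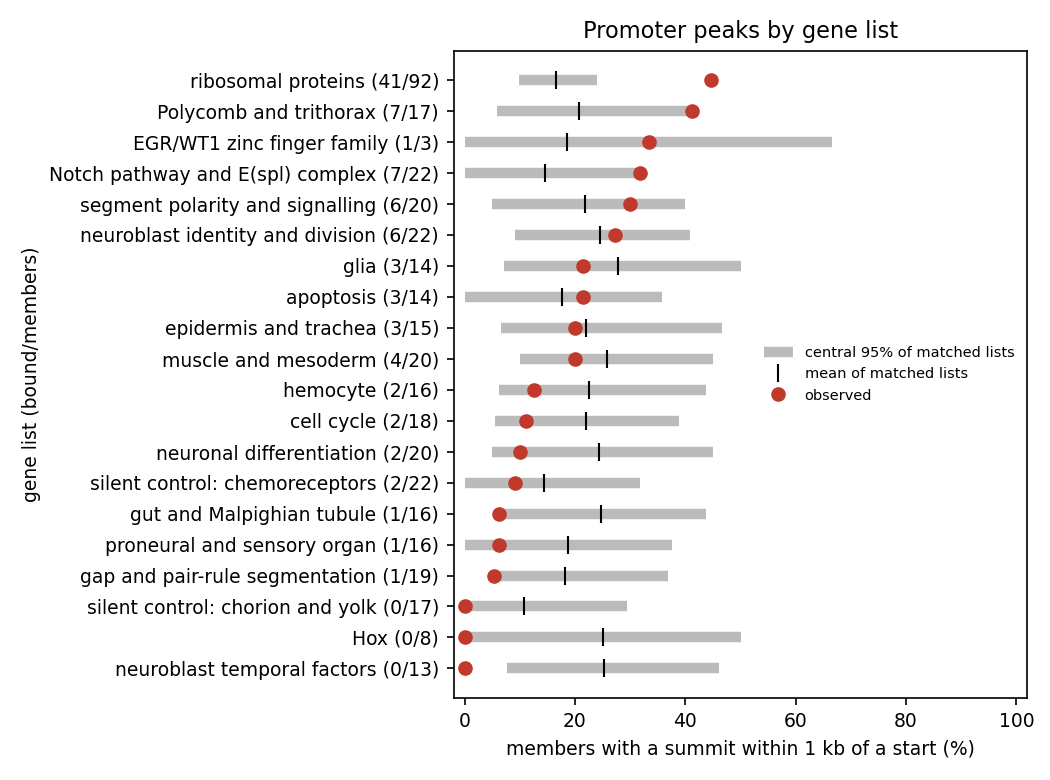
Share of each list's members with a summit within 1 kb of a start (x axis, percent), one list per line with bound and total members. Red points are observed, black ticks the mean and grey bars the central 95% of 10000 matched random lists. Ribosomal protein genes, at 44.6%, lie above their matched range, and neuroblast temporal factors, at 0%, lie below theirs without passing after adjustment.

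Genes of neuroblasts and of the Notch pathway, through which neuroblast and sensory organ fates are set, did not pass the test. The test was run on whole embryos and covers only summits within 1 kb of a protein-coding start, 58.1% of the pooled peaks. Among neuroblast identity and division genes, 6 of 22 were bound against a matched mean of 5.41 (two-sided permutation p = 0.928). They included numb (signal 410, promoter, 2L:9449581), brat (signal 320, intron, 2L:19165192), par-6 (signal 212, promoter, X:17702900, nearer to a start of CG8188) and dlg1 (signal 178, promoter, X:11390790). The numb peak had a signal of 294 in replicate 2 and no overlapping peak in the ranked list of replicate 1. Among Notch pathway and E(spl) complex genes, 7 of 22 were bound against 3.19 (permutation p = 0.051, adjusted permutation p = 0.34). The co-repressor gene gro (signal 312, promoter, 3R:26042515), E(spl)m3-HLH (signal 198, promoter, 3R:26021440), E(spl)mdelta-HLH (signal 131, promoter, 3R:25996621) and mam (signal 120, intron, 2R:14008490) had the highest signals. The peak of E(spl)mdelta-HLH lay 1000 bp from its start and nearer to CG43116. None of the 13 neuroblast temporal factors was bound, against a matched mean of 3.29 (permutation p = 0.0438, adjusted permutation p = 0.34). With each peak given to the nearest start at any distance, 3 of the 13 were bound against 3.50 (permutation p = 1). By the same rule, 8 of 22 neuroblast identity and division genes were bound against 5.36 (permutation p = 0.282). Notch pathway and E(spl) complex genes had 8 of 22 bound against 4.23 (permutation p = 0.0794). The family of klu itself had 1 of 3 members bound, klu, against 0.559 (permutation p = 0.924). Of the proneural and sensory organ genes, 1 of 16 was bound, cpo (signal 127, intergenic), against 2.99 (permutation p = 0.319).

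Among Polycomb and trithorax genes, which encode chromatin regulators, 7 of 17 were bound against a matched mean of 3.52 (two-sided permutation p = 0.0822, adjusted permutation p = 0.411). Besides ph-p, these included brm (signal 693, promoter, 3L:15983021, nearer to a start of Arl1), E(z) (signal 361, promoter, 3L:10638066) and ph-d (signal 308, intergenic, X:2124077). When each peak was given to the nearest start at any distance, 9 members were bound and the list passed (adjusted permutation p = 0.022). The segment polarity and signalling list had 6 of 20 members bound against 4.36 (permutation p = 0.507), with spi (signal 329), aos (signal 197), mid (signal 166) and sty (signal 131). By the nearest start at any distance, 11 of its 20 members were bound against 5.50 (unadjusted permutation p = 0.0178, adjusted permutation p = 0.119).

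The remaining lists did not pass. Muscle and mesoderm genes had 4 of 20 members bound (mbc, tin, sls and htl, signals 228, 193, 139 and 79.5, the peak of mbc nearer to a start of Nup98-96), glial genes 3 of 14 (moody, loco and htl, signals 423, 93.3 and 79.5), and apoptosis genes 3 of 14 (Diap1, hid and p53, signals 182, 175 and 95.2). Epidermis and trachea genes had 3 of 15 members bound (crb, bnl and trh, signals 143, 118 and 106), cell cycle genes 2 of 18 (CycE and Cdk4, signals 169 and 83.6), and neuronal differentiation genes 2 of 20 (elav and fne, signals 463 and 71.6). Hemocyte genes had 2 of 16 members bound (Hml and ush, signals 85.2 and 79.8), gut and Malpighian tubule genes 1 of 16 (Hnf4, signal 121), and gap and pair-rule genes 1 of 19 (bcd, signal 123). No member was bound among 8 Hox genes, against a matched mean of 2.01, or among 17 chorion and yolk genes, against 1.84. With the nearest start at any distance, 4 of the 8 Hox genes were bound against 2.41 (permutation p = 0.391). Of the 22 chemoreceptor genes, which like the chorion and yolk genes served as a control silent in most embryonic cells, 2 were bound (Gr63a and Or43b, signals 89.5 and 84.5, the peak of Gr63a nearer to a start of Lamtor4), against 3.15. Within 1 kb, the lowest two-sided permutation p among these lists was 0.118 and the lowest adjusted permutation p was 0.47.

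The sequence at summits was rich in A and T, and the EGR/WT1-type site was rare. The mean GC content within 50 bp of the summit was 36.0 ± 0.205% (SE, 3087 peaks) against 42.8 ± 0.189% in flanks 1 kb away, and from flank to summit it dropped by 7.74 percentage points in replicate 1 (43.1% to 35.4%) and dropped by 9.46 in replicate 2 (43.0% to 33.5%). GC content at the summit was 30.3 ± 0.364% in the strongest quintile of the peaks and 43.2 ± 0.467% in the weakest quintile. Of 8192 7-mers, 440 were more frequent at summits and 489 less frequent (exact McNemar tests, Benjamini-Hochberg adjusted over all 7-mers), and 64 of the more frequent consisted of A and T only. The list of replicate 1 alone gave 234 more and 141 less frequent 7-mers, and that of replicate 2 alone 542 more and 922 less frequent. Windows of 100 bp either side of the summit gave 663 more and 986 less frequent, and GC-matched random positions, a comparison added after seeing the data, 72 more and 12 less frequent.

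**Figure D4:**
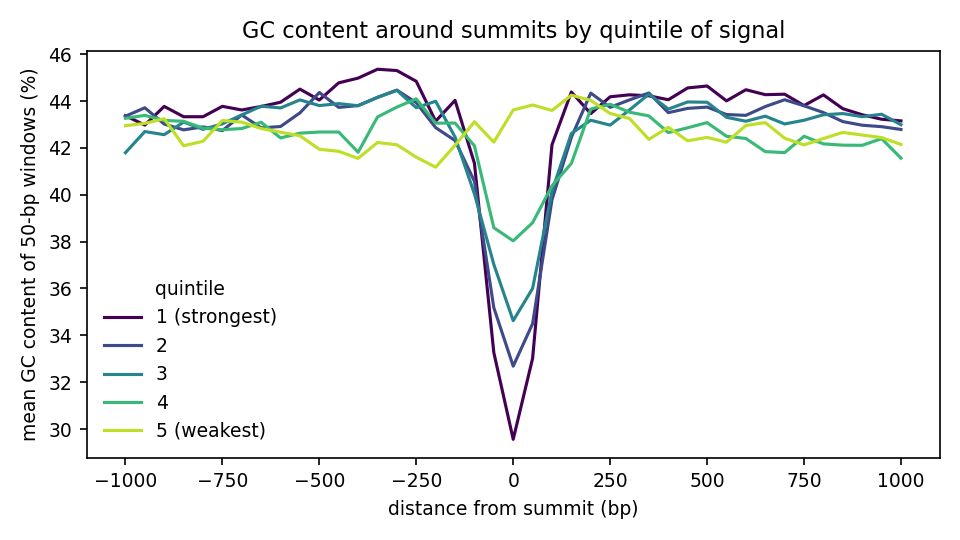
Mean GC content of 50-bp windows (y axis, percent) by distance from the summit (x axis, bp), for the quintiles of the pooled peaks ranked by signal. Within 50 bp of the summit, GC content is 30.3% in the strongest quintile and 43.2% in the weakest.

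The Klu/EGR motif GTGGGYG lay within 50 bp of 136 of 3087 summits (4.41%) and in 104 flanks (3.37%), a difference of 1.04 percentage points (exact McNemar test, p = 0.0407). Adjusted over the 15 motifs, the exact McNemar p was 0.102. The longer site GCGTGGGYG was present at 26 summits and 5 flanks (exact McNemar test, p = 0.000192), and against random positions of the same GC content the shorter motif was present at 4.41% of summits and 2.49% of positions (exact McNemar test, p = 3.48e-05). Those positions were not matched on distance to a start. In the lists of replicate 1 and replicate 2 alone the difference from the flanks was 0.132 and -0.156 percentage points, and in the pooled peaks above the median signal it was -0.583. In the weakest quintile of the peaks the motif was at 5.997% of summits and 2.92% of flanks (exact McNemar test, p = 0.011), and in the strongest quintile at 2.75% and 3.24% (exact McNemar test, p = 0.743). These p-values by quintile were not adjusted.

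Of the 15 motifs, 5 passed the adjusted threshold, 2 more frequent and 3 less frequent at summits than in flanks. With the flank 2 kb away, 4 were more frequent (DREF, homeodomain, Motif 1 and Caudal) and 1 less frequent (the Snail/Esg E-box). In windows of 25 bp either side of the summit, an alternative added for all motifs after seeing the data, 0 passed, and the lowest adjusted exact McNemar p was 0.0799. Against GC-matched random positions, a comparison added after seeing the data, 3 were more frequent (Klu/EGR, DREF and Motif 1) and 0 less frequent. Neither the flanks nor these positions were matched on distance to a start, so a motif common at promoters in general could pass. That possibility was not tested. The site of DREF, a promoter-binding factor of proliferation genes, was at 1.33% of summits against 0.259% of flanks (41 against 8, exact McNemar test, adjusted p = 2.95e-05). In windows of 25 bp it was at 19 summits and 6 flanks (exact McNemar test, adjusted p = 0.11). The homeodomain core TAATTA was at 9.33% against 6.19% (exact McNemar test, adjusted p = 4.28e-05), but against GC-matched random positions its difference was -0.486 percentage points (exact McNemar test, adjusted p = 0.723). In windows of 25 bp that difference from the flanks was 0.939 (exact McNemar test, adjusted p = 0.154). Less frequent at summits than in flanks were the Twist E-box (3.53% against 4.96%, exact McNemar test, adjusted p = 0.03), the Snail/Esg E-box (1.59% against 2.53%, exact McNemar test, adjusted p = 0.0475) and the CA repeat (2.14% against 3.14%, exact McNemar test, adjusted p = 0.0491). With the flank 2 kb away, the Twist E-box (exact McNemar test, adjusted p = 0.107) and the CA repeat (exact McNemar test, adjusted p = 0.649) no longer passed. The Snail/Esg E-box did not pass in the list of replicate 1 alone (exact McNemar test, adjusted p = 0.0526) or without overlapping secondary peaks (exact McNemar test, adjusted p = 0.0778). The Twist E-box did not pass in the conservative list (exact McNemar test, adjusted p = 0.0965), in the list of replicate 1 alone (exact McNemar test, adjusted p = 0.291) or in windows of 100 bp (exact McNemar test, adjusted p = 0.122). The CA repeat did not pass in the list of replicate 2 alone (exact McNemar test, adjusted p = 0.281). Against GC-matched positions these differences were -0.454, -0.162 and 0.0972 percentage points, and the lowest adjusted exact McNemar p of these motifs was 0.581. Against the flanks, the GAGA factor, Zelda, Su(H), proneural E-box, Motif 1, GATA, Grainyhead, Pho and Caudal motifs did not pass, and the lowest of their adjusted exact McNemar p-values was 0.146. Under alternatives, 6 of these 9 passed at least once. The proneural E-box was less frequent at summits by 2.32 and 1.87 percentage points in the lists of replicate 1 and replicate 2 alone (exact McNemar test, adjusted p = 0.0131 and 0.00473) and by 2.98 in the peaks above the median signal (exact McNemar test, adjusted p = 0.000138). Motif 1 was more frequent in windows of 100 bp (exact McNemar test, adjusted p = 6.26e-05) and with the flank 2 kb away (exact McNemar test, adjusted p = 0.0153). Caudal was more frequent with that flank (exact McNemar test, adjusted p = 0.0249), in the list of replicate 2 alone (exact McNemar test, adjusted p = 0.0213), above the median signal and without overlapping secondary peaks. The GAGA factor motif was less frequent in the conservative list, above the median signal and without overlapping secondary peaks, Zelda less frequent in windows of 100 bp and Pho more frequent in the conservative list. Against GC-matched positions, the proneural E-box was instead at 3.92% of summits and 2.82% of positions (exact McNemar test, adjusted p = 0.066). Signs also turned for the GAGA factor, Zelda and Caudal motifs, with differences of 0.324, 0.0324 and -1.20 percentage points that did not pass. Motif 1 stayed more frequent there, while Pho was nearly equal, at 30 summits and 29 positions.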

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

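Peaks in data that the comparisons did not use: the pooled list held 39 peaks outside the main arms. They are listed because such peaks were present at all, and no control level shows whether their number is unusual. Of these, 6 lay on Y and 33 on scaffolds assigned to X. The lists of replicate 1 and replicate 2 held 42 and 24 such peaks.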

How the results depend on the processing

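The settings without overlapping secondary peaks, without the klu region, with GC-matched positions for all motifs and 7-mers, and with windows of 25 bp for motifs other than Klu/EGR were chosen after seeing the data. Replicate overlap (70.5 to 82.2%), signal correlation (rho 0.602 to 0.768), the promoter excess (33.9 to 46.7 percentage points) and the stronger signal at promoters (0.26 to 0.38 in log2) kept their direction and side of the threshold under every alternative run, and chromosome 4 stayed below expectation. Taking the peaks above the median signal leaves fewer peaks by construction (1543), with 1460 genes bound within 1 kb, 1 arm, 8 motifs and a Klu/EGR difference of -0.583 percentage points. That difference was 0.587 with the conservative list, 1.17 in windows of 100 bp, 0.907 with the flank 2 kb away, 0.356 in windows of 25 bp and 0.593 without overlapping secondary peaks, and none of these passed even unadjusted, as the main value did (adjusted over the motifs, the main value did not pass). The Klu/EGR difference did pass against GC-matched random positions (1.91, exact McNemar test, unadjusted p = 3.48e-05) and with the longer site (0.680, exact McNemar test, unadjusted p = 0.000192). With gene number as the expectation 4 arms passed. Given the nearest start at any distance, 2 gene lists passed. Windows of 100 bp either side of the summit gave 663 enriched 7-mers. GC-matched positions gave 72, with 3 motifs passing (3 more and 0 less frequent) and a homeodomain difference of -0.486. Windows of 25 bp gave 0 motifs, with DREF and homeodomain differences of 0.421 and 0.939, and the flank 2 kb away gave 5 (4 more and 1 less frequent). Leaving out each replicate gave 1511 to 2561 peaks, 1 to 2 arms, a Klu/EGR difference of -0.156 to 0.132, 234 to 542 enriched 7-mers, 1250 to 2076 genes bound within 1 kb, 0 to 1 gene lists by the matched-list permutation test (2 lists in each at an unadjusted p under 0.05) and 3 to 6 bound neuroblast genes. Beyond the smaller lists, the cause was not tested. Depth limits how many peaks each list holds and is unknown. No paired analysis was possible because there is 1 group.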

Other observations

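The tests of mitochondrial ribosomal proteins, of peak number and extra copies around klu, and of filtering on chromosome 4 were chosen after their results had been seen in part. When the 7-mers were compared with random positions of the same GC content, also chosen after seeing the data, 72 were more frequent at summits and 12 less frequent. The most significant were CACAGTG, at 2.69% of summits against 0.518% of positions (exact McNemar test, adjusted p = 1.95e-08), and CCCCCGC, at 2.14% against 0.421% (exact McNemar test, adjusted p = 6.36e-07). Others of the 10 most significant included CAGTGTA, CAGTGCA, ACAGTGG and CACTGTA, which share the core CAGTG or its reverse complement, and CACCCCC. The site of Motif 1, a promoter element bound by M1BP, was at 0.648% of summits against 0.0648% of such positions (exact McNemar test, adjusted p = 0.000606). These positions were not matched on distance to a start, while 51.3% of summits lay in promoters against 13.6% of random positions. A motif or 7-mer common at promoters in general could therefore pass, which was not tested.

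One hypothesis was that the peaks at ribosomal protein genes reflect promoters of broadly expressed genes in general. Of 73 mitochondrial ribosomal protein genes, 23 had a peak within 1 kb of a start, against a matched mean of 6.62 (two-sided permutation p = 2e-04, the smallest these draws can give, adjusted permutation p = 6e-04), with mRpL41, mRpS10, mRpS23 and mRpL23 having the highest signals (1708, 1130, 959 and 886); the peak of mRpS23 is the one nearest to CenG1A. Of 32 proteasome genes, 5 were bound against 4.62 (permutation p = 1), and of 32 aminoacyl-tRNA synthetase genes, 7 were bound against 5.66 (permutation p = 0.662). These lists leave open whether broad expression is the shared property, since among the added lists only that of the mitochondrial ribosome passed. Expression was not analysed here.

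The region within 20 kb of klu held 17 pooled peaks, and none of 13338 overlapping windows of the same length elsewhere on the arms held as many (0%), with 16 as the highest count and 1 as the median; without overlapping secondary peaks, a count added after seeing the data, the region held 15 and the highest count elsewhere was 14. In the pooled list, the spacing of peaks elsewhere therefore argues against chance clustering, though by a narrow margin. Of the 17 peaks, only the promoter peak at 3L:11009339 overlapped a peak in the lists of both replicates, against 41.3% of all pooled peaks. The region held 7 peaks in the list of replicate 1, 5 in that of replicate 2 and 10 in the conservative list. These counts were not compared with other windows. Extra copies of the locus brought by the transgene may raise all signal there: peaks below the threshold had a median signal of 23.2 in replicate 1 against 13.3 in other windows, above each of 12496, and 17.7 against 13.9 in replicate 2, at percentile 97.2. The 47 other windows with 10 or more peaks had a median percentile of 44.4 in replicate 1 and 75.2 in replicate 2. Windows were taken every 10 kb, so neighbours overlapped and the 47 need not be separate regions. Of the 47 windows, 0 and 5 reached the value of the klu region. In replicate 1 this argues against a background common to regions dense in peaks. In replicate 2 the dense windows tended to be raised as well, so a partly shared background stays open there. Binding of Klu to its own gene stays open, as 1 of the 17 peaks had the Klu/EGR motif against 4.40% of all other peaks (Fisher's exact test, p = 0.536).

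Chromosome 4 was nearly free of peaks. Filtering of the thresholded list was not the whole cause, since the ranked list already held 57 peaks there against 1339 expected by length, a ratio of 0.0426. Repeat content did not account for it either: in 26 windows of 50 kb, chromosome 4 held 46 ranked peaks against a mean of 1057 in windows of other arms with the same masked share within 5 percentage points, a ratio of 0.0435, and the lowest of 1000 matched draws was 777. What remains open, and was not tested, is how the peak caller or its control treated this small chromosome, and the distinct chromatin of chromosome 4. The design has no second group, so no biological explanation was tested.

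The low GC content at summits could come from where in promoters the summits lie, or from the libraries. At promoters, summits had a GC content of 35.2% against 39.6% at the same distances from starts of genes without a peak, a difference of -4.46 ± 0.407 percentage points (SE, 1500 promoter peaks), so position alone does not account for it. The drop was not shared by all ranked peaks: summits of the 129810 below the threshold were 3.80 percentage points richer in GC than their flanks. Those peaks lay elsewhere, 12.9% in promoters and 19.2% in coding exons, against 51.3% and 1.49% of the pooled summits. The comparison was not matched on class, so it cannot decide whether the libraries had a GC bias. Such a bias, at all peaks or only at strong ones, stays open. Open or AT-rich promoter sequence as such also stays open and untested, since the design has no second group.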
